A study of Mus musculus with 4 samples.

How the data were processed

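RNA from mouse ES cells was measured on 4 single-colour Affymetrix arrays, 2 of Snai1 knockout cells and 2 of control cells. Per the labels' protocols, cells were cultured with leukaemia inhibitory factor and feeders, total RNA was purified on columns, and biotinylated RNA was prepared with a kit that amplifies from the 3' end. Groups and replicate numbers were taken from the sample titles. The titles of the control samples carry F/F, which the labels do not explain, and their genotype field reads control, but their source name also holds the words knock out. They were taken as control from the title and the genotype, and the direction of every difference rests on these labels. The labels call the 2 samples of each group biological replicates without saying what separated them (cultures, clones or days), so p-values measure the spread between these samples only.

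The deposited values were log2 expression values per probe set, 45101 per array, and ranged from 2.56 to 14.78. The submitters' processing notes name RMA, which corrects background, normalises between arrays by quantiles and summarises the probes of a probe set, and limma, both without a version. The order and settings of these steps are not given in the sources used here. The medians of the 4 arrays lay between 4.91 and 4.95, so the values were used as deposited. Quantile normalization of this kind sets the arrays' distributions equal and can hide a shift shared by most genes. It does not remove differences in RNA integrity. No genome build was named, so no coordinates are given.

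Probe sets were named through GEO's platform annotation of August 2016, with symbols checked by gene ID against a RefSeq gene table (assembly GRCm38.p6), which held 34754 of them and changed 0. Of the probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none. After the 64 Affymetrix control probe sets were set aside, 34945 probe sets with 1 symbol remained. Each gene was represented by its brightest probe set, the one with the highest mean over the 4 arrays, which left 18193 genes. Probe sets with several symbols or none were tested only as unnamed probe sets. Where another probe set, at a mean of 6 or more, of a named gene past the threshold had the opposite sign or a much smaller difference, its value is given. Genomic span was taken from the RefSeq table for 18145 genes (99.7%).

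Knockout was compared with control with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 4 arrays and without covariates. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05 and no fold minimum. Differences are knockout minus control on the log2 scale with limma's moderated standard error, and ± marks either this standard error (SE) or the standard deviation of the 2 arrays (SD). Background was read from 24 control probe sets of Bacillus transcripts over the 4 arrays (2.91 to 4.77, median 3.27). Lists of genes were fixed before the data were examined and covered pluripotency, lineages, epithelial and mesenchymal genes, feeder fibroblasts, signalling, stress, metabolism, imprinting and chromatin. The lists held 585 entries, of which 36 were not measured. The 25 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. A list of sex-linked genes was read as a sample check and not tested as a list.

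The genes named in the text followed a rule fixed before the data were examined. Snai1 was given first, then the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, leaving out gene models without a common name. For each list, up to 4 members with the largest change past the threshold were named, or the 1 member with the largest change where none passed. Pou5f1, Sox2, Nanog, Cdh1, Epcam, Vim, Snai2, Zeb1 and Zeb2 were given whatever their values. Genes named outside this rule are marked as chosen after their values were seen.

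Alternatives fixed before the data were examined were an intensity trend or a robust fit in eBayes, a further quantile normalization, centring each array on its median, 2 filters on dim genes, the mean of all probe sets of a gene, all probe sets tested singly, a fold minimum, limma's treat test, a replicate block, and leaving out each array in turn. Removal of each array's trend with gene span and mean level (loess, span 0.3) and the mean level of the feeder markers as a covariate were added after seeing the data. The feeder marker level followed the replicate number in both groups. So this covariate cannot separate feeder cells from whatever the number marks. The test was checked on simulated values for the 18193 genes of this comparison. It found 0 of 67 genes changed by 0.5, 6 of 67 changed by 1 (8.96%) and 44 of 66 changed by 2 (66.7%) on the log2 scale, with 0 false calls among 50. A raised pluripotency list was found, with 0 of the other lists called. The simulated errors were independent between genes and few genes were changed, whereas 4353 real genes had an unadjusted limma p under 0.05. So these shares do not give the power or the false calls of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. GC content was not examined, since probe sequences were not used here.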

Results

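Transcript levels were measured with Affymetrix mouse arrays, after labelling from the 3' end of the RNA, in mouse embryonic stem (ES) cells, pluripotent cells that self-renew in culture and can form every tissue of the embryo. The cells were grown with leukaemia inhibitory factor, a cytokine that maintains self-renewal, on a layer of feeder cells. There were 4 arrays, 2 from Snai1 knockout cells and 2 from control cells, and the labels describe the 2 arrays of each group as biological replicates. Snai1 encodes Snail, a zinc finger repressor known for silencing epithelial genes such as Cdh1 during epithelial-mesenchymal transition. The deposited values were log2 expression values, with array medians of 4.94 and 4.95 in the knockout and 4.95 and 4.91 in the control, and 18193 genes were compared. The number of arrays limits the precision of every comparison, and with 2 arrays per group each gene's error rested on 2 residual degrees of freedom and 5.31 prior degrees of freedom pooled across genes. Over genes, which are not independent replicates, Pearson's r was 0.994 within the knockout pair, 0.994 within the control pair and 0.986 to 0.990 between the groups.

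Control probe sets placed at the 3' and 5' ends of abundant transcripts, differed between the groups. For Actb, which encodes beta-actin, the 3' probe set exceeded the 5' probe set by 0.95 ± 0.21 (log2, SD, n = 2) in the knockout and by 3.02 and 2.97 in the control arrays, a difference of 2.04 with a standard error of 0.15. For Gapdh, a glycolytic enzyme, the gap was 0.34 ± 0.09 (SD, n = 2) in the knockout and 1.36 ± 0.17 (SD, n = 2) in the control, a difference of 1.02 with a standard error of 0.14. For Pcx, a pyruvate carboxylase with dimmer control probe sets, the gap differed by 0.06. For Tfrc, the transferrin receptor, it was larger in the control by 1.01, with a 5' probe set at a mean of 3.47, within the background range, and a 3' probe set that differed by -0.89, knockout minus control. The bacterial and phage spike-ins, which are added to the RNA after labelling, differed in this gap by 0.15 or less in size over 8 pairs of probe sets.

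**Figure D1:**
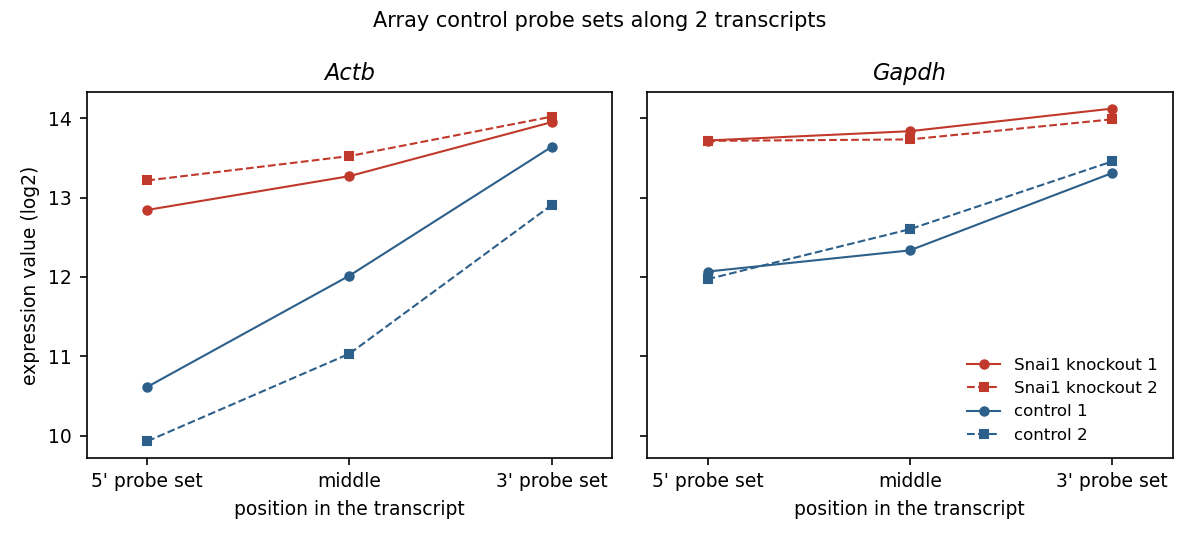
Log2 expression value (vertical axis) of the 5', middle and 3' control probe sets (horizontal axis) of Actb and Gapdh, with a line for each of the 4 arrays. The 3' minus 5' gap of Actb was 1.11 and 0.80 in the knockout arrays and 3.02 and 2.97 in the control arrays.

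The knocked-out gene was examined first. Snai1 was represented by 1 probe set at 3.79 and 4.04 in the knockout arrays and 4.41 and 4.69 in the control arrays. The knockout lay lower by a log2 difference of -0.63 ± 0.16 (SE), which did not pass the threshold (limma adjusted p = 0.0692). These levels all lay within the range of 2.91 to 4.77 given by 24 control probe sets for Bacillus transcripts that no mouse RNA should bind. Whether this probe set lies in the deleted part of the gene is not given in the sources used here, so its level does not by itself check the labels.

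Among the 18193 genes, 754 (4.14%) differed between knockout and control at an adjusted p of 0.05, of which 360 were higher and 394 lower in the knockout. The rises were larger than the falls. The median log2 difference was 0.94 among the higher genes and -0.76 among the lower genes, and 138 genes rose but only 32 fell by a log2 difference of 1 or more. In all 754 genes both knockout arrays lay beyond both control arrays, which follows from passing this threshold with 2 arrays per group and does not add to the calls. Over all genes the groups did not overlap for 52.3%, against 33.3% by chance for groups of 2. The median difference over all genes was -0.02. Among genes at a mean of 6 or more, the higher genes spanned a median of 8.83 kb in the genome and the lower genes 52.8 kb, against 23.2 kb for genes that did not pass. This count depended on each array: it was 27 without knockout replicate 1, 19 without knockout replicate 2, 50 without control replicate 1 and 4 without control replicate 2, each with the lone array assumed to vary like the remaining pair. It was 321 (224 higher, 97 lower) when all probe sets of a gene were averaged in place of taking the brightest.

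The largest rise was that of Prrc2c, whose brightest probe set was at 11.17 ± 0.19 (SD, n = 2) in the knockout and 7.82 ± 0.95 (SD, n = 2) in the control, a log2 difference of 3.34 ± 0.38 (SE, adjusted p = 0.0186). Another bright probe set of Prrc2c differed by 0.14 (adjusted p = 0.773). Bsg, which encodes basigin, a partner of monocarboxylate transporters, rose from 8.33 ± 0.30 to 10.93 ± 0.13 (SD, n = 2 each), a 6.07-fold difference (adjusted p = 0.00474). Tecr, a reductase of very-long-chain fatty acid elongation, rose by 2.29 ± 0.14 (SE), and its other bright probe set rose by 1.56 ± 0.13 (SE). Ppp1r11, an inhibitory subunit of a protein phosphatase, rose by 2.10 ± 0.17 (SE), whereas its other bright probe set differed by -0.03. The transcription factor Klf5 rose by 2.32 ± 0.32 (SE) and Mdk, the secreted growth factor midkine, by 1.99 ± 0.15 (SE). The remaining large rises were those of Cenpx, a centromere protein (2.02), Cox6b2, a cytochrome oxidase subunit (1.94), Lsm2, an RNA-binding Sm-like protein (1.93), Get3, which delivers tail-anchored proteins to the endoplasmic reticulum (1.88), Mlf2 (1.88) and Pfn1, the actin-binding protein profilin (1.86). The adjusted p of these 12 genes lay between 0.00474 and 0.0283, and the same knockout arrays had the smaller Actb 3' minus 5' gap, by 2.04.

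The largest measured fall was that of Hsf2, a heat shock transcription factor, from 6.82 ± 0.14 in the control to 4.19 ± 0.03 in the knockout (SD, n = 2 each; adjusted p = 0.00344). Pacc1, a proton-activated chloride channel, fell from 6.66 ± 0.15 (SD, n = 2) in the control to 4.52 and 4.53 in the knockout arrays (adjusted p = 0.00474). In the knockout both genes lay within the range of the Bacillus control probe sets, so no fold is given and their rank among the falls is uncertain. Dimmer probe sets, at a mean under 6, did not show these falls. They differed by 0.20 for Hsf2 and by -0.06, -0.09, 0.18 and 0.11 for Pacc1. That at -0.06 was at 5.29 in the knockout and 5.34 in the control, above the background range. Sp3, a zinc finger transcription factor, fell by 1.75 ± 0.16 (SE, adjusted p = 0.00844), Agtr2, an angiotensin receptor, by 1.58 ± 0.15 (SE, with 1 knockout array at 4.69, within the background range), and Dcun1d1, which acts in cullin neddylation, fell from 7.73 ± 0.30 to 6.23 ± 0.10 (SD, n = 2 each). The 2 other bright probe sets of Dcun1d1 differed by -0.14 and 0.48. Further falls were found for Septin10 (-1.47), Tgfbr3, the TGF-beta co-receptor betaglycan (-1.19), the Y-linked gene Uty (-1.19), the splicing regulator Mbnl2 (-1.16), Ttc39b (-1.15), the junction protein Cxadr (-1.15) and Rabgef1 (-1.15). Other bright probe sets differed by 0.13 for Cxadr, by -0.18 for Mbnl2 and by -0.77, -0.12 and 0.00 for Ttc39b. Of the 57 named genes past the threshold, 3 (Bsg, Hsf2 and Pacc1) passed with each of the 4 arrays left out in turn. After the trend of each array with gene span and mean level was removed, an alternative chosen after seeing the data, 13 of the 57 no longer passed. Tgfbr3 (-0.98 ± 0.20, SE, adjusted p = 0.0506) and Uty (-1.001 ± 0.221, SE, adjusted p = 0.0607) were among them. With all probe sets of a gene averaged 28 no longer passed, including Prrc2c, Pacc1 and 8 of the other 11 largest falls. Such a mean also takes in dim probe sets. Ccl2 and Mael, also among the 28, have a single probe set each and kept their differences.

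In the list of core and naive pluripotency genes, 7 of 27 measured members rose in the knockout and none fell. With all probe sets of a gene averaged 4 rose (Klf5, Utf1, Nanog and Pou5f1), and with the replicate block 8 rose and 2 fell. With the feeder marker level as a covariate, an alternative chosen after seeing the data, 8 rose and 4 fell. That covariate followed the replicate number, so it is not a separate adjustment for feeder cells. Klf5 rose by 2.32, Utf1, a chromatin-associated factor of undifferentiated cells, by 1.62 ± 0.15 (SE, adjusted p = 0.00905), Lin28a, an RNA-binding regulator of let-7 microRNAs, by 1.34 ± 0.14 (SE, adjusted p = 0.0162) and the orphan nuclear receptor Esrrb by 1.05 ± 0.20 (SE, adjusted p = 0.0426). Nanog rose from 10.46 and 10.45 in the control arrays to 11.39 ± 0.20 (SD, n = 2) in the knockout, a log2 difference of 0.94 (adjusted p = 0.0340). Pou5f1, which encodes Oct4, rose from 12.17 ± 0.07 to 13.02 ± 0.07 (SD, n = 2 each), a log2 difference of 0.85 (adjusted p = 0.0340). The remaining member past the threshold, Dppa3, which was named after its values were seen, differed by 0.78 ± 0.16 (SE). Sox2, the partner of Oct4, was at 12.03 in the knockout and 12.05 in the control (log2 difference -0.02 ± 0.13, SE). Other bright probe sets differed by 0.22 for Lin28a, 0.10 for Esrrb and 0.61 for Utf1. Adjusted over the list alone, 8 members were higher and 2 lower. As a list these genes did not pass the threshold (camera adjusted p = 0.108, and adjusted p = 0.936 with an estimated correlation), with a median difference of 0.03, but with camera the list passed without knockout replicate 2 (adjusted p = 0.000921), without control replicate 2 (0.0371) and with the feeder covariate (0.00523). The control arrays, in which these 7 genes were lower, had the larger Actb 3' minus 5' gap, by 2.04. No member passed without knockout replicate 1, knockout replicate 2 or control replicate 2, and 2 passed without control replicate 1.

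**Figure D2:**
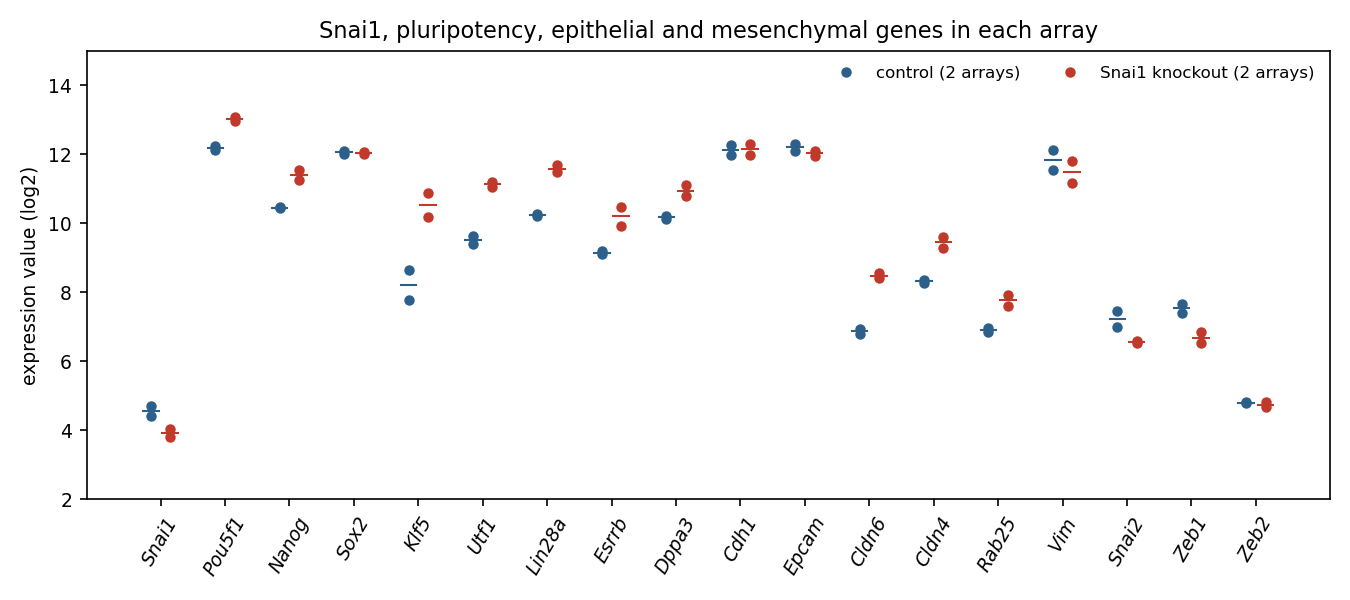
Log2 expression value (vertical axis) of Snai1 and of selected pluripotency, epithelial and mesenchymal genes (horizontal axis). Points are the 2 arrays of each group, blue for control and red for Snai1 knockout, and short lines are group means. The points of Pou5f1, Nanog, Klf5, Utf1, Lin28a, Esrrb and Dppa3 lie higher in both knockout arrays, and those of Sox2 and Cdh1 overlap.

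Among 29 measured epithelial genes, 3 rose and none fell. These were the tight junction claudins Cldn6 (1.61 ± 0.14, SE, adjusted p = 0.00745) and Cldn4 (1.12 ± 0.16, SE, adjusted p = 0.0283) and the epithelial trafficking GTPase Rab25 (0.87 ± 0.16, SE, adjusted p = 0.0405). Cdh1, the E-cadherin gene that Snail represses in other settings, was at 12.14 ± 0.23 in the knockout and 12.12 ± 0.20 in the control (SD, n = 2 each), a log2 difference of 0.02 that was smaller than its standard error of 0.17. Epcam, an epithelial adhesion molecule, differed by -0.17 ± 0.15 (SE, adjusted p = 0.560). Adjusted over the list alone, 4 members were higher, and the list as a whole did not pass (camera adjusted p = 0.167). The same knockout arrays had the smaller Actb gap, and after removal of the gene span trend Cldn4 (0.87 ± 0.18, SE, adjusted p = 0.0502) and Rab25 (0.76 ± 0.16, SE, adjusted p = 0.0540) no longer passed. Without control replicate 2, none of the 29 members passed, and 1 passed without each of the other arrays.

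Among 23 measured mesenchymal genes, 2 fell in the knockout and none rose. These were Zeb1, a zinc finger repressor of epithelial genes (-0.84 ± 0.17, SE, adjusted p = 0.0453), and the integrin Itgb3 (-0.82 ± 0.17, SE, adjusted p = 0.0487, with 1 knockout array at 4.71, within the background range). Neither passed after removal of the gene span trend (-0.63 ± 0.15 and -0.76 ± 0.16, SE, adjusted p = 0.0683 and 0.0580), nor when all probe sets of a gene were averaged, nor with any 1 array left out. The list's median difference was -0.31, and 4 members were lower adjusted over the list alone (camera adjusted p = 0.751). With the replicate block 2 members rose and 7 fell, and with the feeder covariate 3 rose and 4 fell. The list's mean level was 8.15 and 7.60 in knockout replicates 1 and 2 and 8.32 and 7.81 in control replicates 1 and 2. The feeder markers below order the arrays alike, so feeder signal was not told apart from that of ES cells. Vim, the intermediate filament vimentin, was at 11.48 ± 0.44 in the knockout and 11.83 ± 0.40 in the control (SD, n = 2 each), a difference within the spread between replicates (adjusted p = 0.486). In the family of transcription factors of epithelial-mesenchymal transition, 1 of 16 measured members, Zeb1, passed. Adjusted over that list alone 1 member was higher and 4 were lower (camera adjusted p = 0.751). The 4 lower members include the knocked-out Snai1 itself, whose values lay within the background range. They also include Prrx1, named after its values were seen, which is a feeder marker too. Snai2 differed by -0.66 ± 0.18 (SE, adjusted p = 0.0813) and Zeb2, near the background range, by -0.06 ± 0.14 (SE). These control arrays had the larger Actb gap, by 2.04.

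Markers of fibroblasts, the usual feeder cells, were included because feeder RNA can enter such samples. Of 24 measured markers 1, the chemokine gene Ccl2, rose (0.77 ± 0.16, SE, adjusted p = 0.0456), and none fell. The list's median difference was -0.19, and adjusted over the list alone 1 member was higher and 1 lower (camera adjusted p = 0.853). The mean level of these markers differed more between replicates than between groups: it was 7.57 and 6.94 in knockout replicates 1 and 2 and 7.76 and 7.17 in control replicates 1 and 2. In both groups, 18 of the 24 markers were higher in replicate 1. With the replicate block 1 marker rose and 9 fell. Ccl2 did not pass when all probe sets were averaged (0.77, adjusted p = 0.0541), after removal of the gene span trend (0.56 ± 0.15, SE, adjusted p = 0.0895) or with any 1 array left out. It has a single probe set, so averaging left its own values unchanged and moved only its error and adjusted p.

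Lists of lineage markers had few members past the threshold, and none of these lists passed as a whole in this comparison. Among 20 formative and primed epiblast genes Cldn6 rose and none fell, with 2 higher adjusted over the list alone (camera adjusted p = 0.611, and 0.0148 with all probe sets of a gene averaged). No member passed among 17 primitive streak and early mesendoderm genes (adjusted p = 0.611), where the largest difference was that of Fgf17 (0.77 ± 0.26, SE). None passed among 27 genes of mesoderm, heart, endothelium and blood (adjusted p = 0.853), with Tek, an endothelial receptor, at a knockout mean of 4.68, within the background range, and 5.58 in the control (adjusted p = 0.0541), or among 24 extraembryonic endoderm genes (adjusted p = 0.853), with Pdgfra at -0.84 ± 0.19 (SE, adjusted p = 0.0550). In these 3 lists none passed adjusted over the list alone either. Of 16 definitive endoderm genes 2 rose, and 2 passed adjusted over the list alone (camera adjusted p = 0.502). They were Trh, which encodes thyrotropin-releasing hormone (1.63 ± 0.25, SE), and the serine protease Tmprss2 (1.33 ± 0.18, SE), which was at 4.08 in the control, within the background range.

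Among 22 neuroectoderm and neuron genes Stmn2, a neuronal microtubule regulator, rose (0.79 ± 0.15, SE) and Pax6, an eye and neural transcription factor, fell (-0.68 ± 0.13, SE), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.751). The other bright probe set of Stmn2 differed by -0.24. Pax6 differed by 0.0013 when its probe sets were averaged, the others of which lay within or just above the background range. Among 22 trophectoderm and trophoblast genes Esrrb rose and the receptor Fgfr2 fell (-0.94 ± 0.13, SE), as also adjusted over the list alone (camera adjusted p = 0.751). Mael, a germ line gene of transposon silencing, fell (-0.85 ± 0.16, SE) among 18 germ line and two-cell-stage genes, and 3 were lower adjusted over the list alone (camera adjusted p = 0.611). None of 30 Hox genes passed, including adjusted over the list alone (camera adjusted p = 0.897), and Hoxd13, named for the largest measured difference, was at 5.52 in the control and 4.64 in the knockout (adjusted p = 0.0617), within the background range, so its rank is uncertain. Stmn2, Pax6, Fgfr2, Mael and Tmprss2 did not pass with any 1 array left out, and the groups differed in the Actb gap by 2.04.

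Over all genes, 5 targets of 3 signalling pathways passed, and none of the 3 lists passed as a whole. Of 17 Wnt and beta-catenin targets 2 fell, the receptor Ror1 (-0.85 ± 0.16, SE) and the Wnt effector Lef1 (-0.76 ± 0.15, SE), and 2 were lower adjusted over the list alone (camera adjusted p = 0.853). Of 17 BMP and TGF-beta targets 1 fell, the Smad corepressor Skil (-0.85 ± 0.14, SE), with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.829). Of 16 feedback targets of FGF and ERK signalling 2 fell, Spred1 (-0.78 ± 0.16, SE) and the ERK phosphatase Dusp6 (-0.76 ± 0.15, SE), with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.751). The adjusted p of these 5 genes lay between 0.0340 and 0.0461. The other bright probe sets of Spred1 differed by -1.11, -0.87 and -0.01. None of the 5 genes passed with any 1 array left out, and after removal of the gene span trend Ror1 (-0.68 ± 0.15, SE, adjusted p = 0.0602), Lef1 (-0.51 ± 0.17, SE, adjusted p = 0.140) and Spred1 (-0.56 ± 0.14, SE, adjusted p = 0.0778) did not pass. The control arrays, where these genes were higher, had the larger Actb gap, by 2.04.

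Among 22 interferon-induced genes 2 passed, both higher in the knockout. Ifitm3, which restricts virus entry, rose by 1.49 ± 0.17 (SE, adjusted p = 0.0186). Oasl2 differed by 0.86 ± 0.14 (SE, adjusted p = 0.0340), but all 4 of its values lay within the background range, so it is not read as a rise. Adjusted over the list alone 5 were higher and 1 lower (camera adjusted p = 0.219). Of 26 imprinted genes Mirg, a maternally expressed RNA (1.27 ± 0.22, SE, with another probe set at 1.49), and Nnat (1.08 ± 0.15, SE) rose and the amino acid transporter Slc38a4 fell (-0.70 ± 0.14, SE, with another probe set at -0.30), with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.853). Of 20 p53 targets Gtse1 rose (1.01 ± 0.14, SE) and Sesn1 fell (-0.73 ± 0.15, SE, with other probe sets at -0.67 and -0.36), with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.751). After removal of the gene span trend Slc38a4 (-0.48 ± 0.12, SE, adjusted p = 0.0775) and Sesn1 (-0.51 ± 0.13, SE, adjusted p = 0.0745) did not pass. None of 24 cell cycle genes passed, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.853), and the largest difference was that of the cyclin Ccne2 (-0.76 ± 0.17, SE, adjusted p = 0.0542). None of these called genes passed with control replicate 2 left out, and the knockout arrays had the smaller Actb gap, by 2.04.

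The glycolytic enzyme gene Pfkl (1.20 ± 0.17, SE) was the called member of 21 hypoxia and glycolysis genes, with 4 higher adjusted over the list alone (camera adjusted p = 0.751). Of 22 genes of the unfolded protein and stress response, Hmox1, which encodes heme oxygenase (0.75 ± 0.14, SE), and the stress transcription factor Atf4 (0.70 ± 0.13, SE) rose, with 3 higher adjusted over the list alone (camera adjusted p = 0.751). The other bright probe set of Atf4 differed by -0.41. Atf4 did not pass after removal of the gene span trend (0.47 ± 0.13, SE, adjusted p = 0.0952) or with all probe sets of a gene averaged. Fdps, an enzyme of isoprenoid synthesis (0.85 ± 0.14, SE), rose among 16 cholesterol synthesis genes, with 1 higher adjusted over the list alone (camera adjusted p = 0.967). None of 27 regulators of DNA methylation and chromatin passed, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.751). The largest difference there was that of the Polycomb partner Mtf2 (1.54 ± 0.38, SE, adjusted p = 0.0617), whose other bright probe sets differed by 0.33, -0.57 and -0.65. Pfkl, Hmox1, Atf4 and Fdps did not pass with any 1 array left out, and the knockout arrays had the smaller Actb gap, by 2.04.

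**Figure D3:**
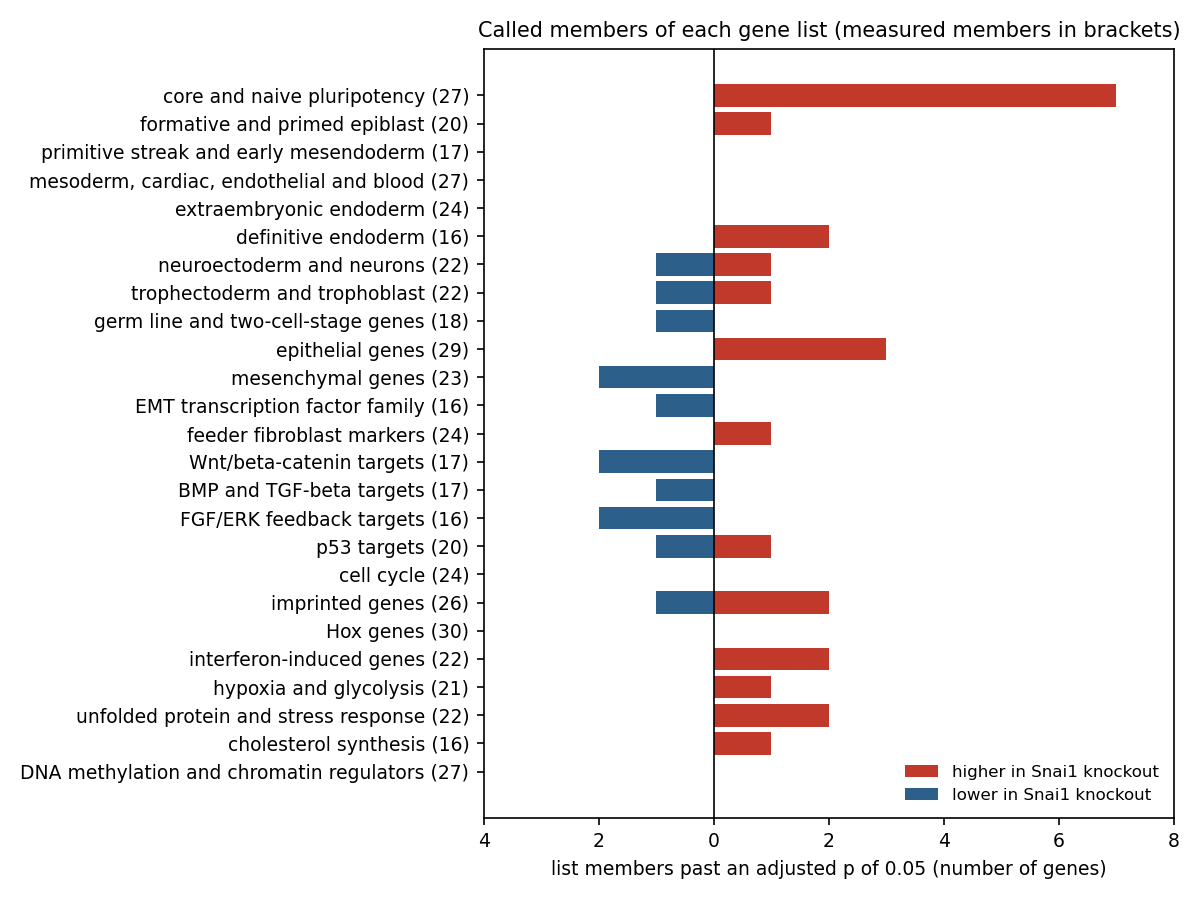
Number of members past an adjusted p of 0.05 (horizontal axis) in each of the 25 gene lists, with measured members in brackets. Red bars count genes higher and blue bars genes lower in the knockout. The pluripotency list holds the most, with 7 higher and 0 lower of 27.

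Over the 25 lists, 0 passed the threshold with camera at its preset correlation, 3 had an unadjusted p under 0.05 (pluripotency at 0.00433, epithelial at 0.0134 and interferon-induced at 0.0263), 0 passed with an estimated correlation and 0 passed with fry, which tests movement in 1 direction. With fry's test of change in either direction 19 passed. In 9 lists the median, the mean and the test differed in sign. These were the lists of mesoderm, extraembryonic endoderm, epithelial-mesenchymal transition factors, Wnt targets, BMP and TGF-beta targets, p53 targets, imprinted genes, Hox genes and hypoxia. The pluripotency and epithelial lists passed without knockout replicate 2 (adjusted p = 0.000921 and 0.000576), and the pluripotency, mesenchymal and feeder lists passed without control replicate 2 (adjusted p = 0.0371, 0.0371 and 0.0415). With the feeder covariate, which followed the replicate number, the pluripotency and epithelial lists passed (adjusted p = 0.00523 each).

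As a check of the samples, Y-linked and X-linked genes were read in both groups. The Y-linked gene Eif2s3y was at 9.33 ± 0.18 in the knockout and 9.74 ± 0.25 in the control (SD, n = 2 each). Uty, also Y-linked, was at 6.15 ± 0.22 and 7.34 ± 0.35, and Xist, the X-inactivation RNA, at 6.65 ± 0.06 and 6.94 ± 0.70. The other probe sets of Xist lay within the background range in both groups (3.43 and 3.98, and 3.78 and 3.98). Kdm5d (3.71 and 3.61), Usp9y (3.71 and 3.83) and Tsix (4.07 and 4.23) lay within the background range in both groups.

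Differences also varied with the genomic span of the gene. Over 9472 genes at a mean of 6 or more, Spearman's rho between span and the difference was -0.34, across genes, which are not independent replicates. With these genes ordered by span and divided into 10 bins of equal size, the median difference was 0.14 in the bin of the shortest spans and -0.30 in that of the longest. Within groups, the difference of replicate 1 minus replicate 2 also varied with span (rho = 0.30).

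**Figure D4:**
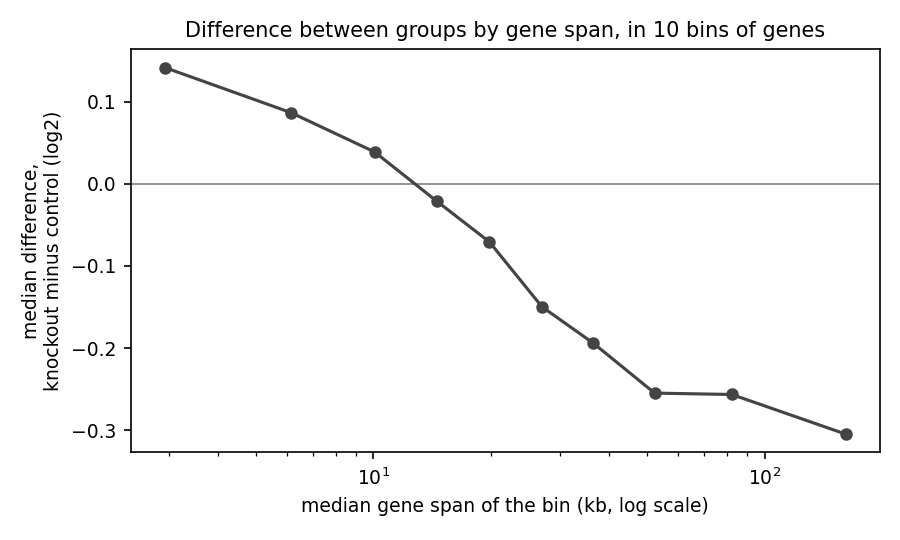
Median log2 difference, knockout minus control (vertical axis), against median gene span in kb on a log axis (horizontal axis), for 10 bins, of equal size, of the genes at a mean of 6 or more. The medians run from 0.14 in the bin of shortest spans to -0.30 in that of the longest.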

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

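The tests of the Actb and Gapdh gap, of the feeder share and of the stem cell share were chosen after the results had been seen, and the tests of gene span and of signal along the transcript were set before their outcomes were known.

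Among control probe sets outside the gene comparison, the 5' probe set of Actb was higher in the knockout by 2.76 (log2, limma adjusted p = 0.0313) and that of Gapdh by 1.70 (adjusted p = 0.0281), whereas the 3' probe sets differed by 0.71 and 0.67 and did not pass (adjusted p = 0.184 and 0.0733). A higher level of the transcripts alone would move both ends alike. The gap of 3' minus 5' was instead larger in the control by 2.04 for Actb, over 2 of its standard errors of 0.15. But the 3' probe sets already lay at 13.27 (Actb) and 13.38 (Gapdh) in the control, and the highest value on any array was 14.78. With less room to rise at the 3' end the gap could narrow too, so a higher transcript level cannot be told apart here. Shorter labelled RNA from the control samples is a candidate explanation: the Gapdh gap was larger in the control by 1.02, both control arrays lay above both knockout arrays for either transcript, and spike-ins added after labelling differed by 0.15 or less in size. Other transcripts did not add to it: the Pcx gap differed by only 0.06 (SE 0.03), and that of Tfrc, larger in the control by 1.01, came with a 3' probe set lower in the knockout (-0.89) and a 5' probe set at background (3.47). Whether the RNA was shorter in the cells, at extraction or through amplification was not tested, and neither was an effect of Snai1 loss itself.

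For the 754 genes past the threshold, a trend with gene span as the whole cause is argued against, since 59.0% of them (445 genes) still passed after its removal. But among all 587 genes that then passed, newly called ones included, 204 were lower in the knockout, against 394 before. A different share of feeder cells would raise the genes of 1 cell type alike, and for the genes higher in the knockout it is argued against as the whole cause: their median was 0.94, against 0.026 (SD 0.72) over 25 pluripotency genes at a mean of 8 or more and -0.23 (SD 0.54) over 20 feeder markers at a mean of 6 or more. For the genes lower in the knockout, with a median of -0.76, a lower share of feeder cells cannot be told apart, since the markers' median of -0.23 lay within their SD of it. Signal that changes along the transcript may account for part of the calls: over 3534 genes, the difference between the 2 brightest probe sets of a gene spread 2.31 times as widely between knockout and control (0.49) as in the wider of the other splits of the arrays (0.21), but that of the brightest probe set itself also spread more widely (0.37 against 0.20), so larger changes read unequally by 2 probe sets can widen it too. The Actb and Gapdh gap and the genotype differed together in these 4 arrays, and an effect of Snai1 loss stays open and untested.

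The 7 pluripotency genes higher in the knockout are the last pattern. A trend with gene span is argued against as the whole cause. The median difference of the 7 genes after its removal was 126% of that before (1.32 against 1.05). These medians fell on different genes, Esrrb before and Utf1 after, so they do not show that the differences grew. Esrrb went from 1.05 to 1.32, and Klf5 (2.32 and 2.32) and Lin28a (1.34 and 1.39) hardly moved. Pou5f1 (0.85 to 0.74), Nanog (0.94 to 0.84) and Utf1 (1.62 to 1.32) shrank but still passed. Dppa3 no longer passed (0.78 ± 0.16 before and 0.58 ± 0.15 after, SE, adjusted p = 0.0765), as its difference shrank and its standard error hardly changed. A lower share of stem cells in the control would lower all such genes, and it is argued against as the whole cause of these 7 rises. Over all 25 members at a mean of 8 or more the median difference was 0.026 (SE 0.18), with 15 higher and 10 lower. Whether the share itself differed is not answered, since quantile normalization can hide a shift shared by most genes. The feeder markers, at a median of -0.23, leave such a difference open. Signal that changes along the transcript cannot be told apart from a change in these genes: the other probe sets showed 16.0% of the difference of the brightest, the size predicted if it were the cause, but there were only 3, for Lin28a, Esrrb and Utf1, all higher in the knockout. An effect of Snai1 loss stays open and untested.

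Among probe sets without a single gene symbol, 28 were higher and 3 lower in the knockout past the threshold, and the largest difference was 3.88 (adjusted p = 0.0227).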

How the results depend on the processing

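The removal of the gene span trend and the feeder covariate were chosen after seeing the data, and the other alternatives before. The 754 genes past the threshold (360 higher, 394 lower) became 481 with an intensity trend (198 lower), 1216 among genes at or above the median level (692 lower), 1219 among genes at 6 or more in 2 arrays (696 lower), 321 with the mean of all probe sets (224 higher, 97 lower), 276 with all 34945 probe sets tested (214 higher, 62 lower), 170 with a log2 difference of 1 or more (138 higher, 32 lower) and 17 with treat (14 higher, 3 lower). The 2 filters test fewer genes, and a fold minimum and treat ask for larger differences; the cause of the others was not tested. With the feeder covariate 3156 passed (1218 higher, 1938 lower), and after removal of the span trend 587 (204 lower). The feeder marker level followed the replicate number, so its count is not independent of that with the replicate block given below. Robust eBayes (893), a further quantile normalization (854) and median centring (786) stayed within 1.5 times. Leaving out 1 array gave 4 to 50 genes, 2 to 46 higher and 2 to 4 lower, from fewer samples: 27 without knockout replicate 1, 19 without knockout replicate 2, 50 without control replicate 1 and 4 without control replicate 2. The replicate block gave 3092 genes (1200 higher, 1892 lower) and 0 lists, and moved Snai1 past the threshold at -0.63 (adjusted p = 0.0109). Pluripotency members past the threshold went from 7 higher to 8 higher and 2 lower, and feeder markers from 1 higher to 1 higher and 9 lower. The block and the feeder covariate each leave fewer residual degrees of freedom than the main fit, so their larger counts are not read as a gain in precision. Deviations of same-numbered arrays correlated at 0.29 over genes, and the second principal component (23.7% of the variance) separated the numbers, but with 2 pairs and no label saying what a number marks they were not taken as pairs.

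With the feeder covariate 5 feeder markers passed upward and 6 downward. The covariate is the mean level of these same markers, so their differences balance by construction. Snai1 also passed with this covariate (-0.72, adjusted p = 0.00239), as did 8 pluripotency genes upward and 4 downward. Over its alternatives its difference stayed negative, with adjusted p from 0.00239 to 0.259. Lists past the threshold numbered 0 in the main comparison, 1 with the mean of all probe sets (formative and primed epiblast, adjusted p = 0.0148), 2 with the feeder covariate (pluripotency and epithelial), 19 with fry in either direction, and 0 to 3 with 1 array left out (2 without knockout replicate 2, 3 without control replicate 2); the causes were not tested. Pax6 reversed with the mean of all probe sets, from -0.68 to 0.0013 (adjusted p = 0.998). That mean takes in its other probe sets, which differed by -0.04, 0.22, 0.43 and 0.08. Their group means lay between 3.32 and 4.94, within or just above the background range. Of the 57 named genes past the threshold, 48 still passed with an intensity trend, 57 with robust eBayes, 56 with quantile normalization, 29 with the mean of all probe sets, 44 after removal of the span trend and 4 to 17 with 1 array left out. Genes near the background of 2.91 to 4.77, such as Snai1, are limited by signal.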

Other observations

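The gene families and single genes in this part were chosen after the results had been seen. Families of genes for mitochondrial proteins had positive median differences, knockout minus control. Of 75 measured mitochondrial ribosomal protein genes 7 rose, such as Mrpl4 (1.19 ± 0.16, SE) and Mrpl27 (1.01 ± 0.19, SE), and 2 fell (Mrps9 at -0.67 and Mrpl44 at -0.62). Their median difference was 0.28 (camera adjusted p = 1.14e-07 over 9 families, and adjusted p = 0.508 with an estimated correlation). Of 76 subunits of the respiratory chain complexes 7 rose, Cox6b2 (1.94) and Atp5mpl (0.97) the most, and none fell, with a median of 0.15 (camera adjusted p = 3.38e-05, and adjusted p = 0.508 with an estimated correlation). Of 39 proteasome subunits 3 rose, with Psmb7 at 1.78 ± 0.15 (SE). Of 42 cytosolic ribosomal protein genes 1 fell, Rpl27a (-1.05 ± 0.14, SE), and the family's median was 0.08. Of 329 measured zinc finger genes of the Zfp series, 15 fell and 4 rose, with a median of -0.22 (camera adjusted p = 0.000209, and adjusted p = 0.508 with an estimated correlation). Medians after removal of the gene span trend were 0.20 for the mitochondrial ribosomal proteins, 0.10 for the respiratory chain, -0.01 for the cytosolic ribosomal proteins and -0.20 for the Zfp genes. Of the 9 families, 8 passed at the preset correlation and 0 with an estimated correlation. The same knockout arrays had the smaller Actb 3' minus 5' gap, by 2.04.

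Other genes past the threshold were Ly6e, a lymphocyte antigen family member (1.81 ± 0.13, SE, adjusted p = 0.00533), Ifitm2, a relative of Ifitm3 (1.74 ± 0.14, SE, adjusted p = 0.00718), Epop, a Polycomb-associated gene of ES cells (1.71 ± 0.15, SE, adjusted p = 0.00718), and Kitl, the ligand of the receptor Kit (-1.13 ± 0.20, SE, adjusted p = 0.0385).

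Probe sets of the same gene could move apart. In Malat1 the brightest probe set differed by -0.66 and the next by 3.41, in Ctcf by -0.70 and 2.51, in Rbm39 by -0.57 and 2.54 and in Rest by -0.37 and 2.35. Other probe sets at a mean of 6 or more had the sign of the brightest in 116 of 145 cases (80.0%) for genes higher in the knockout, in 188 of 258 (72.9%) for genes lower, and in 61.1% for genes that did not pass.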
